A study of Arabidopsis thaliana with 7 samples.

How the data were processed

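Single-cell RNA sequencing was carried out by the authors on root protoplasts of 7-day-old Arabidopsis thaliana Col-0 seedlings treated with flg22, Pep1, Chitin, SCOOP10 or SCREW1, or with no elicitor (Mock). Per the labels, treatment began 30 min before the roots were harvested and went on through 2.5 h of protoplasting, and the libraries were made with the 10x Genomics 3' v3 chemistry. There were 7 libraries: Mock 1, Mock 2 and 1 library for each of the 5 elicitors. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization. A UMI is a molecular tag that marks a single captured transcript molecule. The submitters' processing notes name Cell Ranger 5.0.1 and the TAIR10 genome build. The file headers name Cell Ranger 3.0.2 for Mock 1, flg22 and Pep1, called the first set here, and Cell Ranger 5.0.1 for Mock 2, Chitin, SCOOP10 and SCREW1, called the second set. The labels give the same batch number for all 7 samples. The matrices list 33610 genes by locus code, of which 28932 are in the reference annotation (TAIR10.1, which keeps the nuclear coordinates of TAIR10), used for symbols and positions.

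Cells were kept with at least 500 genes, at least 1000 UMIs and under 5 percent of UMIs from mitochondrial genes. This kept 6814 of 7646 barcodes of Mock 1, 12210 of 12633 of flg22, 9458 of 9980 of Pep1, 5617 of 10112 of Mock 2, 9095 of 11609 of Chitin, 6170 of 9740 of SCOOP10 and 9224 of 10866 of SCREW1. The mitochondrial filter accounted for 4495 barcodes removed from Mock 2 and 423 removed from flg22. Kept cells held between 86293461 (Mock 2) and 339497689 (flg22) UMIs per library, with a median per cell of 15171.5 in Mock 1 and 8895 in Mock 2. A gene with 0 UMIs could lie at up to 0.0348 CPM in Mock 2 and 0.00884 CPM in flg22 (the level of 3 UMIs). All Poisson and Wilson intervals have 95 percent confidence and cover counting error only. The doublet caller Scrublet, run in scanpy 1.11.5, marked 0 cells in every library and found no threshold in SCREW1. It was taken not to have worked, and no cell was removed as a doublet. As an alternative, the 4180 cells with the highest scores were left out.

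Deposited cell types were not available, so classes were rebuilt. The 58588 kept cells were scaled to 10000 UMIs per cell and log-transformed, and 3000 variable genes were reduced to 40 principal components, adjusted for library by the Harmony method and clustered by the Leiden method (leidenalg 0.10.2) at resolution 1, which gave 45 clusters. Before clustering, 3935 genes were left out: those that lay 2-fold from the mean of Mock in any elicitor library, the listed defence genes, and organelle genes. A cluster was named from a fixed list of markers when its leading score was at least 0.5, led the next class by at least 0.15, and rested on at least 3 detected markers. A cluster also stayed unnamed when it was poor in UMIs with none of its own markers among its 10 leading genes, or when those held more markers of another class than its own. These 2 rules left out no cluster at resolution 1, 2 at the finer and 1 at the coarser resolution. Other clusters stayed unnamed. Class names are therefore written as "xylem-like" and so on, and the pericycle-like class rests on just 3 markers. Within the root cap-like class, cluster 24 was led by heat shock genes and cluster 27 by histone genes, as was cluster 22 of the atrichoblast-like class.

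UMI counts were summed per library, and per library and class. Elicitor-treated libraries (5) were compared with Mock (2) by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and a Benjamini-Hochberg threshold of 0.05. Each elicitor was then compared with Mock in a fit with a mean per treatment. The spread there came from the Mock pair alone, which lies in different sets, and each lone elicitor library was assumed to vary as the Mock libraries do. P-values from these fits describe the spread among these 7 libraries only. The same test was run within classes of at least 20 cells in each library, and as a class by treatment interaction on the sums of a class and of all other named cells. No paired analysis was possible because each elicitor has replicate number 1 only, so that the numbers pair no libraries. The sets were used instead as a covariate and for permutation within sets. Gene lists were tested by camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and again with an estimated correlation. Beside camera p-values, medians and means of lists are from the voom values, while counts of higher and lower members are from the edgeR fit. The 13 lists were early pattern-triggered immunity, immune receptors, immune peptide precursors, tryptophan-derived metabolism, phenylpropanoid and lignin biosynthesis, jasmonate, ethylene, salicylic acid, suberin, wall loosening, cell division, heat shock, and leaf photosynthesis as a tissue roots should lack.

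Values for single elicitors were CPM (UMIs scaled to a library total of 1e6) and log2 fold changes with 1 CPM added, against the mean of Mock, against both Mock libraries, and against the Mock library of the same set (Mock 1 for flg22 and Pep1, Mock 2 for the others). These have no test. A fold on this scale understates the change of genes near 1 CPM. Gene counts at 2-fold used a minimum of 10 CPM in all cells and 50 CPM within classes, and class sums were also thinned to 819803 UMIs. List medians were set beside 10000 random lists matched on expression. Shares of cells were compared by exact two-sided permutation over 21 splits of the libraries, and over the 12 splits that exchange labels within a set. Correlations of fold changes were set beside 20 simulations of unchanged groups that share the same Mock libraries.

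The tests, gene lists, cell type markers and the rule for named genes were fixed before the data were examined. All locus codes were assigned by hand then. For 17 of 219 listed genes, among them MIK2, NUT, SCREW1, PROSCOOP10 and most peptide precursors, and for 11 of 109 markers, the name is no symbol or synonym of that locus in the reference annotation, so these codes were not checked. That rule took the 3 members of each list with the smallest p, the 4 largest rises and 2 largest falls per elicitor among genes past the threshold (or at least 2-fold from both Mock libraries where under 5 passed) with at least 10 CPM, the interaction genes with the smallest p, and a fixed set of receptors, precursors and marker genes. Genes named outside that rule are said to have been chosen after their values were seen. Alternatives fixed beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, all deposited barcodes, thinning to the smallest library, equal class shares, organelle genes left out, dispersion from the fit of treated against Mock together with a likelihood ratio test, other cluster resolutions, other CPM minimums and amounts added, and leaving out each library. The Cell Ranger version as a covariate, a class by version term, removal of cells with high doublet scores, and permutation within sets were added after the data were seen. The tests were tried on simulated data with the spread of these libraries, where the treated against Mock fit recovered 10.4 percent of genes changed 4-fold and 56.1 percent of those changed 8-fold, and the fits for single elicitors and for the interaction recovered 0 percent at either size. Of unchanged genes at the spread of these libraries, the treated against Mock fit called 2 of 20549. The fit for single elicitors called 0 of 20726 and the interaction 1 of 19884. With a low simulated spread every fit recovered at least 98.5 percent at each fold. Camera called 10 of 10 raised and 0 of 10 unchanged simulated lists. Genes of those lists were drawn independently, while estimated correlations within the real lists ranged from -0.04 (wall loosening) to 0.82 (receptors). The simulated lists therefore do not show how often camera with the preset correlation calls unchanged lists of correlated genes. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.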

Results

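Roots of Arabidopsis seedlings were exposed to 5 immune elicitors and dissociated into single cells. The elicitors were flg22, a peptide of bacterial flagellin perceived by FLS2, Pep1, an endogenous danger peptide perceived by PEPR1 and PEPR2, chitin, a fungal wall polymer perceived through CERK1 and LYK5, SCOOP10, a plant peptide of a family perceived by MIK2, and SCREW1, a plant peptide perceived by NUT. Each elicitor had 1 library, so no spread within an elicitor could be measured. Libraries fell into 2 sets that followed the Cell Ranger version in the file headers. Mock 2 lay at least 2-fold from Mock 1 in 4007 of 11028 genes, 1805 higher and 2202 lower. Correlation of log CPM across genes was between 0.943 and 0.988 for libraries of the same set and between 0.761 and 0.869 across sets. With the class shares of all libraries made equal, 1472 of 10820 genes lay 2-fold apart between the Mock libraries, 908 higher and 564 lower in Mock 2. Early immunity genes had a median log2 fold change of 1.54 in Mock 2 over Mock 1, and trichoblast markers a median of -3.24. Values against the Mock library of the same set are therefore given beside those against both.

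Across all cells, genes of early immunity, immune receptors, peptide precursors and tryptophan-derived defence metabolism lay higher in the elicitor-treated libraries than in Mock. Where the sets were ignored, this direction depended on Mock replicate 1 for early immunity and receptors, since their medians turned without it. In that setting flg22 and Pep1 were set against Mock 2 alone, a library of the other set. With the Cell Ranger version as a covariate the voom medians of these lists were 0.64 and 0.31. In the early immunity list 23 of 25 measured genes were higher, with a median log2 fold change of 0.76 (camera, adjusted p = 6.42e-07, adjusted p = 0.579 with an estimated correlation). WRKY30, a defence transcription factor on chromosome 5 from 8153115 to 8154710, had 1.94 CPM in Mock 1 and 7.54 in Mock 2, against 9.12 with flg22, 154 with Pep1, 15.6 with Chitin, 248 with SCOOP10 and 381 with SCREW1. In the tryptophan list, which covers camalexin and indole glucosinolates, 21 of 24 genes were higher, with a median of 0.55 (adjusted p = 3.15e-05, adjusted p = 0.579 with an estimated correlation). Its regulator MYB51 had 5.28 and 21.7 CPM in the Mock libraries and 55.6 with Pep1, 74.1 with SCOOP10 and 85.4 with SCREW1, while MYB34 had 10.8 and 3.49 CPM in the Mock libraries and 1.23, 1.81 and 1.83 CPM with Pep1, SCOOP10 and SCREW1.

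Immune receptors were higher in 16 of 19 genes (median 0.48 on voom values and 0.28 in edgeR, camera adjusted p = 3.15e-05, adjusted p = 0.579 with an estimated correlation), and peptide precursors in 12 of 15 (median 0.98, adjusted p = 0.000176, adjusted p = 0.579 with an estimated correlation). Jasmonate genes (17 of 20 higher, median 0.20, adjusted p = 0.0146), salicylic acid genes (13 of 15, median 0.25, adjusted p = 0.00474) and heat shock genes (9 of 9, median 0.32, adjusted p = 0.0146) were also higher, and cell division genes lower (12 of 14 lower, median -0.20, adjusted p = 0.0231). With an estimated correlation the adjusted p = 0.643 for jasmonate and cell division and the adjusted p = 0.579 for salicylic acid and heat shock. The lists of phenylpropanoid (adjusted p = 0.740), ethylene (adjusted p = 0.214, median 0.12), suberin (adjusted p = 0.214), wall loosening (adjusted p = 0.889) and leaf photosynthesis genes (adjusted p = 0.525, median -0.37) did not pass. The sign of the test differed from the mean for phenylpropanoid genes (test down, median -0.13, mean 0.07) and suberin genes (test down, median -0.27, mean 0.04), and from both for wall loosening genes (test up, median -0.11, mean -0.37). In edgeR the suberin median was 0.13. With the Cell Ranger version as a covariate, early immunity (adjusted p = 0.000309), receptors (adjusted p = 0.00466), precursors (adjusted p = 0.00985) and tryptophan metabolism (adjusted p = 0.000770) passed by camera, and with an estimated correlation none of the 4 passed (adjusted p = 0.730 for each). Without Mock replicate 1, 0 lists passed and 5 turned, early immunity to a median of -0.18 (mean 0.01, adjusted p = 0.819), receptors to -0.28 (adjusted p = 0.398), jasmonate to -0.28 (adjusted p = 0.286), salicylic acid to -0.19 (adjusted p = 0.566) and cell division to 0.31 (adjusted p = 0.278). Jasmonate, cell division and heat shock genes also missed the threshold without Chitin (adjusted p = 0.0732, 0.0794 and 0.0538), without SCOOP10 (0.243, 0.0797 and 0.144) and without SCREW1 (0.143, 0.140 and 0.0885), as did salicylic acid genes without SCOOP10 (0.0670) and heat shock genes without Mock replicate 2 (0.109). Ethylene genes passed without flg22 (adjusted p = 0.00737) and without Mock replicate 2 (0.00101), phenylpropanoid genes without Pep1 (0.0239), and suberin genes without Pep1 (0.0486) and without SCREW1 (0.00774). With an estimated correlation 0 lists passed in any of these settings.

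The early immunity gene with the smallest p, WRKY30, had a log2 fold change of 5.20 (SE 1.90) across elicitor-treated (n = 5) against Mock libraries (n = 2) and was higher in 5 of 5 elicitor libraries than in the Mock mean, with an adjusted p of 1.00 in edgeR. No single gene passed this test. In edgeR 0 of 20998 genes passed, with 224 at an unadjusted p under 0.05, and in DESeq2 0 passed, with 584 at an unadjusted p under 0.05. Both fits count the differences between the sets as error. With the Cell Ranger version as a covariate, a fit added after the data were seen, edgeR also passed 0 genes, with 1605 at an unadjusted p under 0.05. The lack of calls therefore does not show that no gene responded. Of the listed genes 0 passed over all genes and 0 adjusted over the list alone. By exact permutation of the mean of the early immunity list over 21 splits the p was 0.429, and over the 12 splits within sets it was 0.333. The 21 splits ignore the sets and cannot give a p below 0.0476. The 12 splits cannot go below 0.0833, so the permutation within sets could not have passed at 0.05.

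Pep1 was accompanied by the widest set of changes in the first set. Against the Mock pair, the only source of spread in this fit, 36 of 21453 genes passed in edgeR, 33 higher and 3 lower, and of the 33, 32 were at least 2-fold higher than Mock 1. With the dispersion from the fit of treated against Mock and a likelihood ratio test in place of the F test 0 passed. AT1G53080 had 0.26 CPM in Mock 1, 0.32 in Mock 2 and 36.3 with Pep1 (log2 fold change 7.06, SE 0.91, adjusted p = 1.98e-10). CYP706A1, a cytochrome P450 gene, had 1.26 CPM in Mock 1 and 109 with Pep1 (log2 5.37, SE 0.90, adjusted p = 1.06e-05). AT4G08780, PP2-A5 and DIR5, a dirigent gene, had 0.01, 0.20 and 0.40 CPM in Mock 1 and 13.3, 11.0 and 10.7 CPM with Pep1. PROPEP1 and PROPEP2, which encode precursors of Pep peptides, had 9.77 and 0.66 CPM in Mock 1 and 65.0 and 34.4 CPM with Pep1, and of these PROPEP2 passed (log2 3.46, SE 0.80, adjusted p = 0.0139). The falls named by rule, IBH1 and HMT3, had 0.62 and 3.23 CPM in Mock 1 against 22.1 and 41.1 CPM in Mock 2, so their calls with Pep1 (0.12 and 1.13 CPM) rested mainly on Mock 2.

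WRKY30, WRKY41, CYP706A1, CYP71A12 and AT1G53080 were called higher with both SCOOP10 and SCREW1. These calls take their spread from the Mock pair alone, and when the dispersion of treated against Mock and a likelihood ratio test replaced both it and the F test, 0 genes passed for either peptide. With SCOOP10 75 genes passed, 53 higher and 22 lower, and with SCREW1 69 passed, 58 higher and 11 lower. The lists of higher genes shared 39, a number with no comparison value, since both were set against the same Mock libraries. WRKY30 lay higher with SCOOP10 (log2 5.82, SE 1.07, adjusted p = 0.000223) and SCREW1 (log2 6.47, SE 1.09, adjusted p = 1.15e-05), as did WRKY41, another transcription factor of the WRKY family, at 1.29 CPM in Mock 2 and 25.3 and 26.1 CPM with the peptides (adjusted p = 2.35e-05 and 8.20e-06). AT2G36690 reached 38.9 CPM with SCOOP10 and 10.1 with SCREW1 from 1.81 in Mock 2. CYP71A12, an enzyme of camalexin synthesis, had 19.9 CPM in Mock 2, 148 with SCOOP10 and 108 with SCREW1 (adjusted p = 0.00811 and 0.0330). Against Mock 2 alone, 52 of the 53 genes higher with SCOOP10 and 55 of the 58 higher with SCREW1 were at least 2-fold higher. Of the lower genes 2 of 22 and 0 of 11 were at least 2-fold lower than Mock 2. The falls named by rule were genes near 0 throughout the second set, with AT1G30870 at 0.32, AGP3 at 0.32 and XTH14 at 0.16 CPM in Mock 2 against 21.8, 26.8 and 23.5 CPM in Mock 1.

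**Figure D1:**
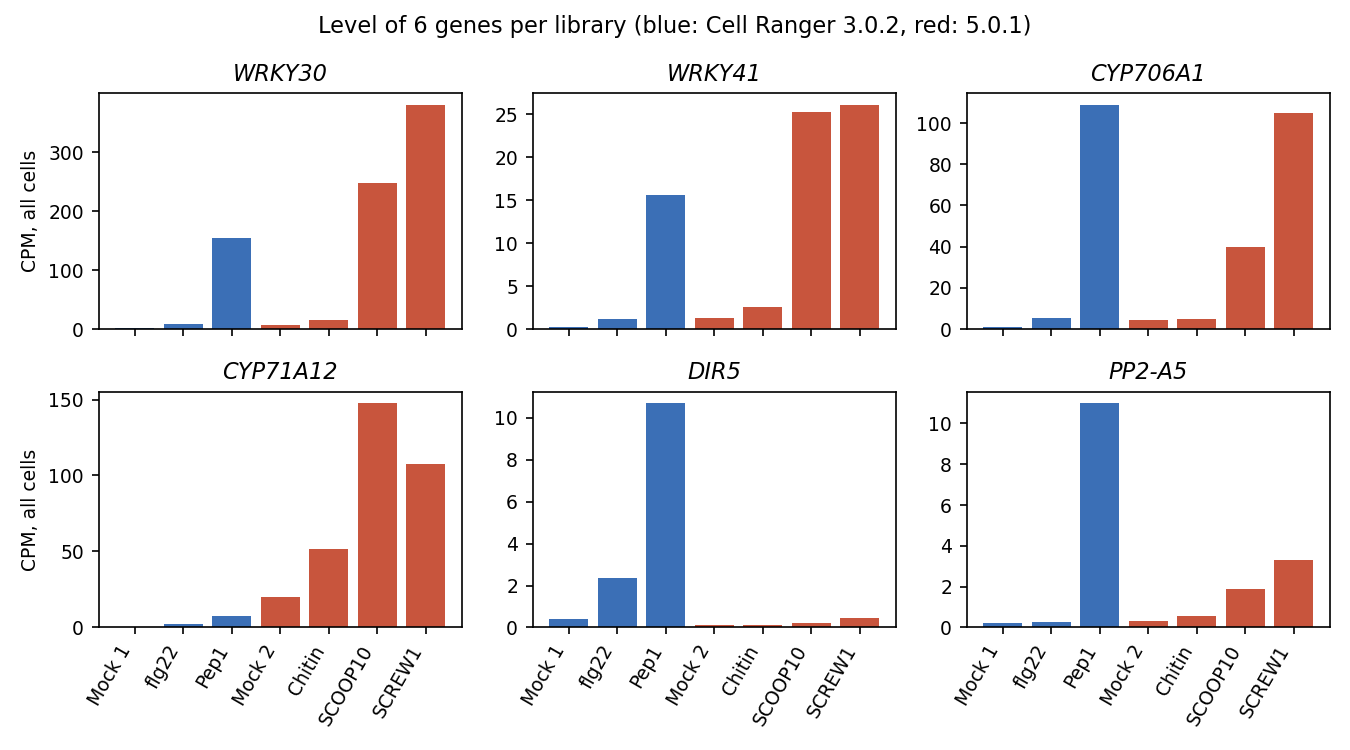
Level in CPM (vertical axis, each panel on its own scale from 0) of 6 named genes in each of the 7 libraries (horizontal axis), with bars coloured by the Cell Ranger version in the file header. WRKY30 is at 1.94 and 7.54 CPM in the Mock libraries and at 154, 248 and 381 CPM with Pep1, SCOOP10 and SCREW1.

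flg22 and Chitin moved few genes. With flg22, 1 gene passed, IBH1, lower at 0.12 CPM against 0.62 in Mock 1 and 22.1 in Mock 2. Named by size alone, the peroxidase gene AT5G64120 had 13.2 CPM with flg22 against 3.49 and 5.93 in the Mock libraries, AT3G54530 13.5 against 3.54 and 1.03, AT2G38823 31.2 against 14.6 and 3.16, and AT2G41730 233 against 113 and 60.7. Lower were AT2G15830 (15.7 CPM against 43.7 and 589) and EFE, an ethylene-forming enzyme (12.5 CPM against 29.9 and 405). With Chitin, 1 gene passed, AT3G29970, higher at 0.79 CPM where both Mock libraries had 0 UMIs, a gene chosen after its value was seen. CYP71A12 had 51.4 CPM with Chitin against 0.56 and 19.9 in the Mock libraries, AT5G40590 268 against 42.1 and 109, and YLS5 68.7 against 33.1 and 33.6. Lower with Chitin were AT5G51890, a peroxidase gene (0.47 CPM against 3.53 and 22.0), and PAL1, which starts phenylpropanoid synthesis (3.32 CPM against 16.4 and 23.8).

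Counts of genes at least 2-fold above, and below, both Mock libraries were 7 and 28 for flg22, 120 and 134 for Pep1, 3 and 12 for Chitin, 189 and 38 for SCOOP10 and 185 and 53 for SCREW1. Without Mock replicate 2 they were 31 and 29 for flg22 and 420 and 215 for Pep1, and without Mock replicate 1 they were 4 and 62 for Chitin, 197 and 182 for SCOOP10 and 219 and 235 for SCREW1, each against the Mock library of the set. The calls depended on the fit. With both the dispersion from the fit of treated against Mock and a likelihood ratio test, 0 genes passed for any elicitor, a change of 2 choices that were not tried apart, and with DESeq2 2, 63, 6, 76 and 89 passed for flg22, Pep1, Chitin, SCOOP10 and SCREW1.

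Against the Mock library of the set, Pep1 had the highest early immunity median of the 5 elicitors at 0.68, with 22 of 25 genes higher, and SCOOP10 had 0.57, with 23 of 25 higher. SCREW1 had 0.14 (18 of 25), flg22 0.02 (13 of 25) and Chitin -0.05 (10 of 25). Tryptophan-derived metabolism had a median of 1.08 with Pep1, 0.84 with SCREW1 and 0.21 with SCOOP10, against -0.03 with flg22 and -0.05 with Chitin. Receptor genes followed with Pep1 (0.88, 18 of 19 higher), among them CERK1 at 66.8 CPM against 19.3 in Mock 1 and MIK2 (AT4G08850) at 74.6 against 27.9. Phenylpropanoid genes had a median of 0.68 with Pep1 and 0.18 with flg22, and of -0.90, -0.43 and -0.50 with Chitin, SCOOP10 and SCREW1. These medians have no test, and Mock 2 over Mock 1 gave 1.54 for early immunity, so that against the mean of Mock the medians were -0.67 for flg22, 0.05 for Pep1, 0.53 for Chitin, 1.09 for SCOOP10 and 0.72 for SCREW1.

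**Figure D2:**
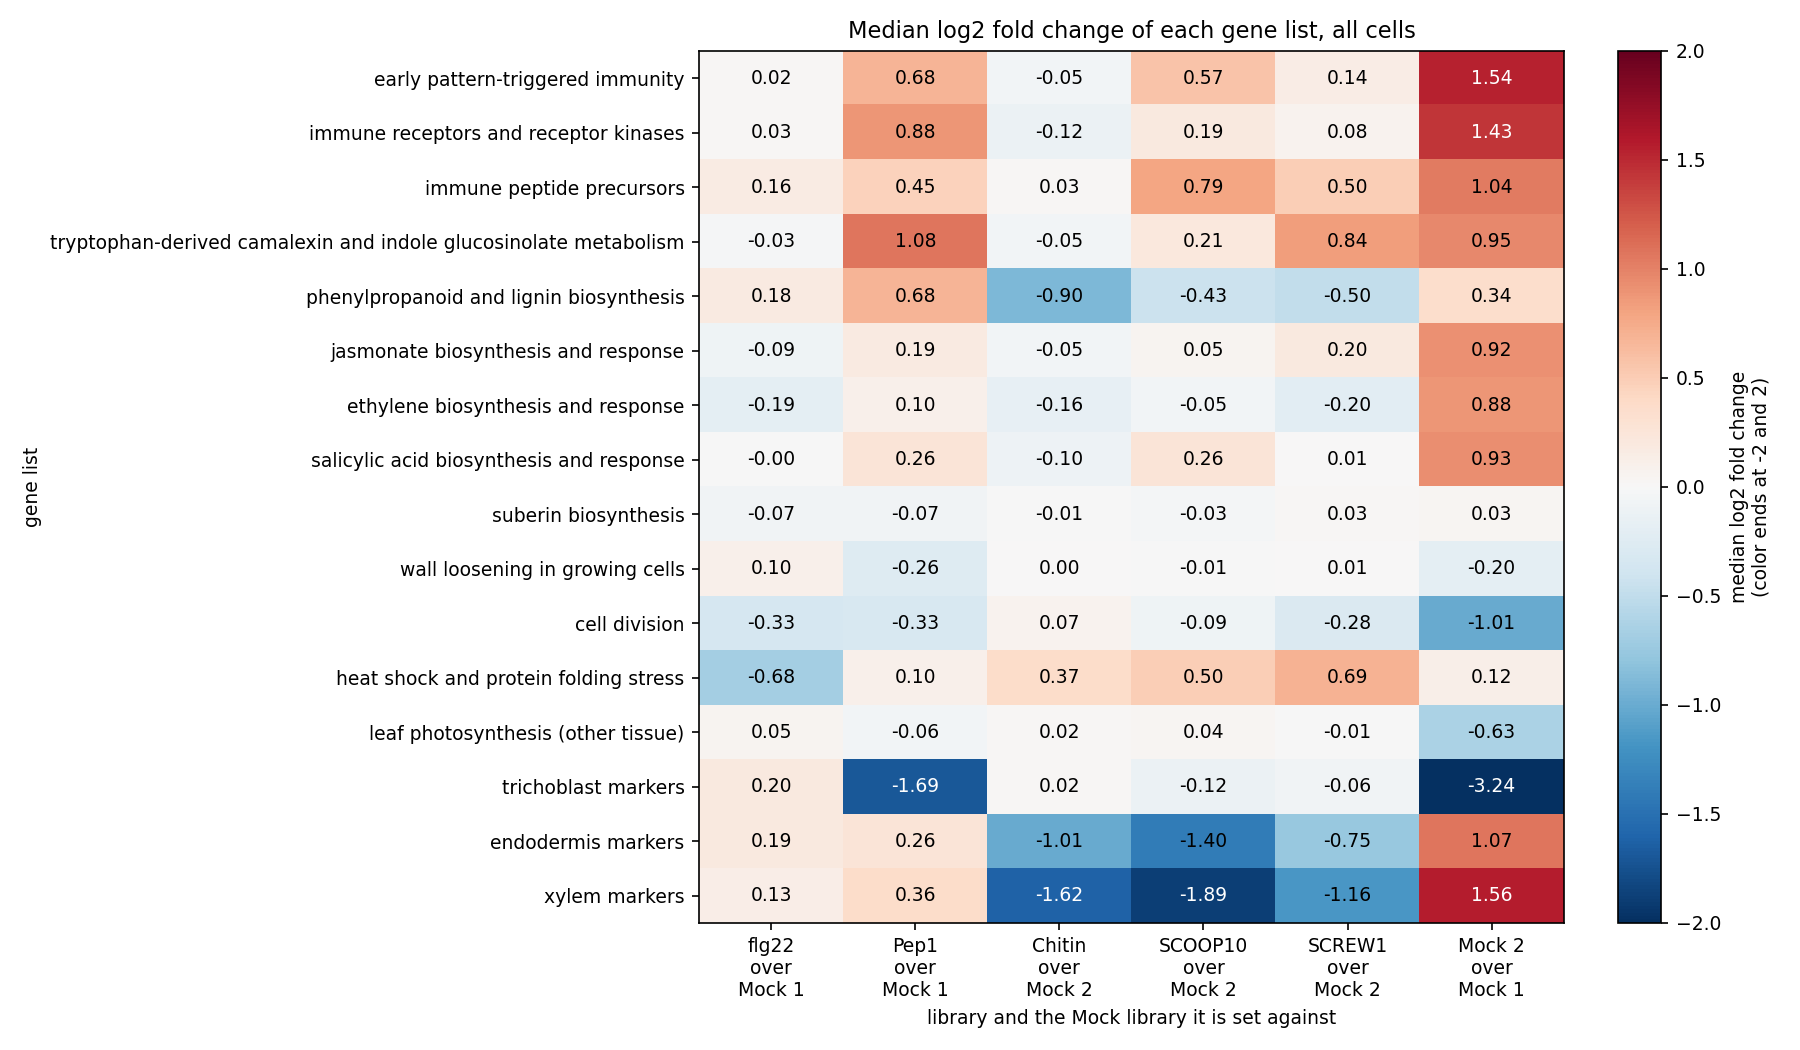
Median log2 fold change of each gene list and of 3 marker lists (vertical axis) for each elicitor library over the Mock library of its set, and for Mock 2 over Mock 1 (horizontal axis), as colour and printed value. The early immunity list is at 0.68 with Pep1 and 0.57 with SCOOP10, and at 1.54 in Mock 2 over Mock 1.

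Markers of differentiated cells were compared between single libraries, with no test. Trichoblast markers, genes of root hair cells, had a median of -1.69 with Pep1 over Mock 1, lower in 11 of 11 genes, against 0.20 with flg22. Within trichoblast-like cells they were lower with flg22 as well, with a median of -0.60 (11 of 11 lower). Endodermis markers had medians of -1.01 with Chitin, -1.40 with SCOOP10 and -0.75 with SCREW1 over Mock 2, and xylem markers -1.62, -1.89 and -1.16. With Pep1 endodermis markers had a median of 0.26 and xylem markers 0.36.

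Receptor transcripts differed in level between elicitors and sets. In Mock 1, FLS2 had 0.38 CPM (95 percent Poisson interval 0.30 to 0.47) and PEPR1 19.1 CPM. In Mock 2, CERK1 had 57.0 and LYK5 44.7 CPM, while MIK2 had 174 and NUT (AT5G25930) 232 CPM, 2 genes whose locus codes were assigned by hand. PEPR2 had 1.72 CPM in Mock 1 and 3.77 in Mock 2. FRK1, a marker of early immunity, reached at most 0.13 CPM in any library. At these very low counts it had 1 UMI in Mock 1 (0.0045 CPM, interval 0.0001 to 0.025) and 37 with Pep1 (0.127 CPM, 0.089 to 0.175). In Mock 2 it had 4 UMIs (0.046 CPM), against 0.087, 0.131 and 0.098 CPM with Chitin, SCOOP10 and SCREW1. WRKY33 had 96.2 CPM in Mock 1 and 450 in Mock 2, with 432 CPM with Pep1 and 729 with SCOOP10. The precursor genes PROSCOOP10 (AT5G44580) and SCREW1 (AT1G06135) had 1.07 and 105 CPM in Mock 2 and 2.58 and 278 CPM with SCOOP10.

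Genes raised at least 2-fold by Pep1 over Mock 1 were shared with those raised over Mock 2 by SCOOP10 (121 genes against 5.83 for independent lists) and by SCREW1 (138 against 7.27), comparisons with no shared Mock library. flg22 shared 16 genes with SCOOP10 (0.286 for independent lists) and 17 with SCREW1 (0.379). Across 9741 genes, which are not independent replicates, fold changes over the Mock library of the set correlated at r = 0.65 (Spearman 0.47) for Pep1 and SCOOP10, 0.62 (0.48) for Pep1 and SCREW1, 0.49 (0.44) for flg22 and SCREW1, 0.20 (0.23) for flg22 and Chitin, 0.17 (0.06) for flg22 and SCOOP10 and -0.02 (0.003) for Pep1 and Chitin. Simulated values for these pairs lay between 0.002 and 0.007. They were near 0 by design, since the pairs share no Mock library, and do not show how far untreated libraries can correlate. The covariance was 0.144 for Pep1 and SCOOP10 and 0.166 for Pep1 and SCREW1, against simulated values of 0.000882 and 0.000546. Pairs that share a Mock library gave 0.73 for SCOOP10 and SCREW1, 0.60 for Chitin and SCREW1, 0.56 for flg22 and Pep1 and 0.35 for Chitin and SCOOP10, against 0.50 simulated. Covariance for SCOOP10 and SCREW1 was 0.143 against 0.0677 simulated. Against the mean of Mock the median r over the 10 pairs was -0.01 (0.60 without Mock replicate 1 and 0.54 without Mock replicate 2), with 0.76 for flg22 and Pep1 and -0.62 for flg22 and SCOOP10, where the simulated values were 0.86 and -0.57.

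Within cell classes, the early immunity list with Pep1 was highest in xylem-like cells (median log2 3.29 over Mock 1, 19 of 20 genes higher), followed by phloem-like (1.99), cortex-like (1.89) and procambium-like cells (1.88), and lowest in root cap-like cells (0.21). WRKY30 with Pep1 went from 0.52 to 247 CPM in atrichoblast-like cells and from 10.8 to 170 CPM in root cap-like cells. SCOOP10 gave the highest early immunity median in atrichoblast-like cells (1.39, 20 of 22 genes higher) and SCREW1 in dividing cells (1.57, 16 of 20 higher). With flg22 the medians were 0.98 in xylem-like, 0.86 in phloem-like and 0.58 in cortex-like cells, and with Chitin the highest was 0.50, in pericycle-like cells. In xylem-like cells jasmonate genes had medians of 2.50 with Pep1 and 2.34 with flg22 (18 of 20 and 20 of 20 genes higher). These are values of single libraries with no test, and the xylem-like class held between 49 and 103 cells per library. Mock 2 over Mock 1, a comparison across the sets with no elicitor, gave early immunity medians from 0.33 to 2.18 over the 11 classes, above 1 in 9. Early immunity class medians of up to 2.18 thus arose across the sets without an elicitor, below the 3.29 of Pep1 in xylem-like cells. How far untreated libraries of the same set lie apart cannot be seen, since each set has a single Mock library. Leaving out the cells with the highest doublet scores, an alternative chosen after the results were seen, kept 53.1 percent of the UMIs of Pep1 xylem-like cells and 67 of 97 cells, and their early immunity median was 2.99 and jasmonate median 1.96. For flg22 it left early immunity medians of 0.34 in xylem-like, 0.45 in phloem-like and 0.50 in cortex-like cells and a jasmonate median of 1.85, for Chitin -0.14 in pericycle-like cells with the highest now 0.31, in dividing cells, and for SCOOP10 and SCREW1 1.37 and 1.62 in the classes named.

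The number of genes at least 2-fold higher at 50 CPM or more also differed by class and elicitor. Pep1 had 895 in xylem-like, 645 in phloem-like and 109 in root cap-like cells. SCREW1 had 494 in dividing cells, SCOOP10 261 in atrichoblast-like, flg22 417 in xylem-like and Chitin 174 in pericycle-like cells. With all class sums thinned to the same number of UMIs the counts were 882, 668, 148, 516, 273, 432 and 192, and without the cells of highest doublet score 825, 591, 105, 497, 269, 320 and 87. Mock 2 over Mock 1 gave 500 in xylem-like cells and 1196 in cortex-like cells, which lay mostly in cluster 15 in Mock 1 and in clusters 12 and 18 in Mock 2. The make-up of classes differed within the second set too. Pericycle-like cells numbered 194 in Mock 2 and 180 with Chitin, but 71 and 106 at the finer resolution. Of the dividing clusters at that resolution, 23 and 42 held 0.98 and 0.21 percent of Mock 2 cells and 0.65 and 0.40 percent of SCREW1 cells.

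**Figure D3:**
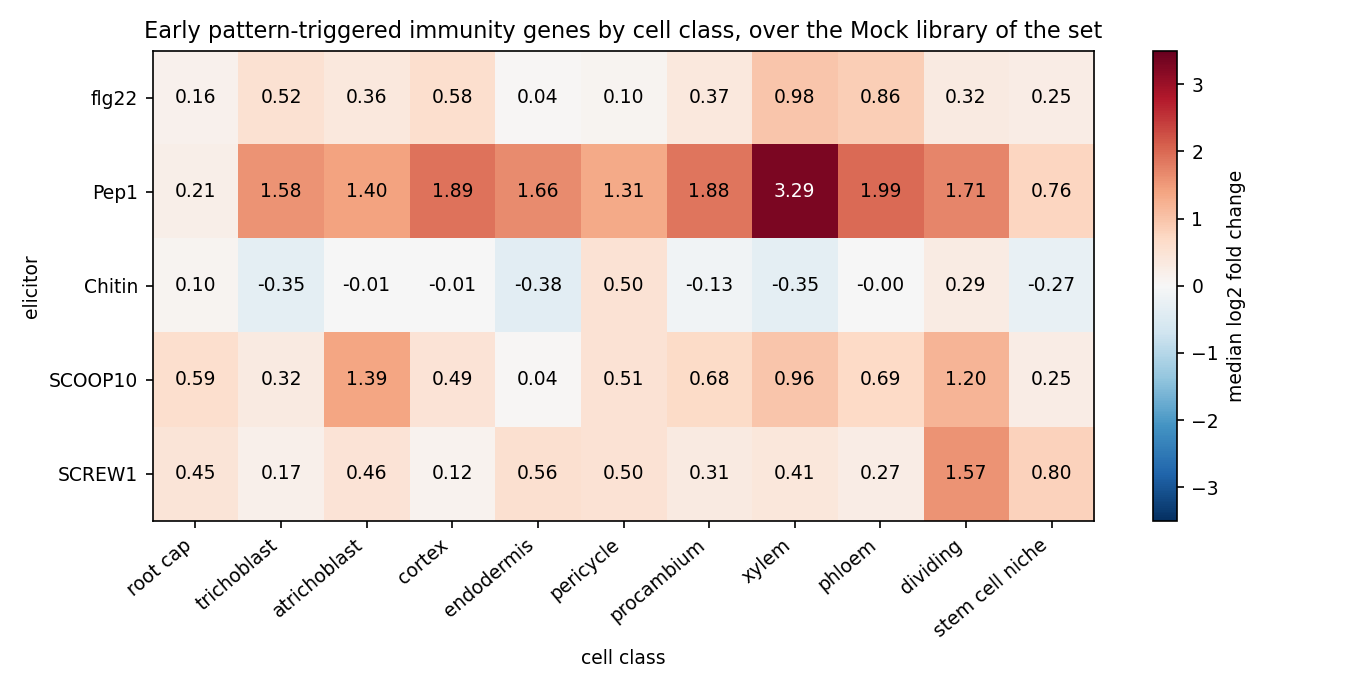
Median log2 fold change of the early immunity list (colour and printed value) for each elicitor (vertical axis) in each cell class (horizontal axis), over the Mock library of the set. Pep1 reaches 3.29 in xylem-like cells and 0.21 in root cap-like cells. Mock 2 over Mock 1, which is not drawn, lies between 0.33 and 2.18.

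In the test of elicitor-treated against Mock within each of 11 classes, 0 genes passed in edgeR in any class, with 115 (endodermis-like) to 578 (atrichoblast-like) at an unadjusted p under 0.05. Without Mock replicate 2, 5 genes passed in phloem-like and 1 in procambium-like cells, and 1 passed in phloem-like cells without Mock replicate 1 and without flg22. With DESeq2, 12 genes passed in atrichoblast-like, 7 in phloem-like, 3 in root cap-like and 3 in xylem-like cells. Whether a response differed between a class and the other cells was tested by the interaction. The peroxidase gene AT3G32980 passed in phloem-like cells (log2 difference -3.13, SE 0.31, adjusted p = 0.0332, edgeR), with 22.6 and 45.6 CPM in Mock 1 and Mock 2 against 2.00 with flg22, 4.18 with Pep1, 3.95 with Chitin, 3.51 with SCOOP10 and 4.58 with SCREW1, lower in 5 of 5 libraries. In endodermis-like cells, mostly of cluster 14 in Mock 1 and of cluster 17 in Mock 2, the gene had 151 and 449 CPM, and within cluster 17 847 and 779 CPM. The call ended at a finer cluster resolution and without any of Mock replicate 1, Mock replicate 2, flg22, Pep1, Chitin, SCOOP10 or SCREW1 (0 genes in the phloem-like class each time), and without Pep1 the xylem gene TED6 passed in xylem-like cells (1 gene). No gene passed in the other 10 classes, with 195 to 615 at an unadjusted p under 0.05. The p-values were adjusted over the genes of each class and not over the classes. On simulated data with the spread of these libraries this test called 1 of 19884 unchanged genes. A single call can therefore arise with no difference in response.

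Shares of root cap-like cells were larger in every library of the second set. Those of atrichoblast-like, cortex-like, dividing and stem cell niche-like cells were smaller in every library of that set. Shares of the other classes, among them trichoblast-like, pericycle-like and phloem-like cells, overlapped between the sets. Root cap-like cells made up 18.23 percent of Mock 1 (Wilson interval 17.3 to 19.2), 14.7 percent of flg22 and 15.0 percent of Pep1, and 39.4 percent of Mock 2 (38.1 to 40.6), 33.0 percent of Chitin, 39.6 percent of SCOOP10 and 27.6 percent of SCREW1. The mitochondrial filter removed more barcodes in the second set, and its cells were shallower. Endodermis-like cells were 8.04 percent with Pep1 against 5.14 percent in Mock 1, and 3.06 percent with SCOOP10 against 5.16 percent in Mock 2. Whether a class differed between elicitor-treated and Mock libraries could not be decided. The smallest p the 21 splits of the exact permutation can give is 0.0476, so a single class could not have passed after adjustment over the classes, and the 12 splits within sets cannot go below 0.0833. The mean difference for root cap-like cells was -2.83 percentage points, and -4.68 within sets (exact p = 0.333). It was -13.4 without Mock replicate 1, 7.74 without Mock replicate 2, -0.01 without flg22, -0.08 without Pep1, -4.59 without Chitin and -6.23 without SCOOP10.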

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

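The tests on untreated libraries, UMIs and receptor levels below, the counts of Casparian strip UMIs in phloem-like cells and their CPM in cluster 17, and the fit with a class by version term, were chosen after the results were seen, and the others before.

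AT3G32980, a peroxidase gene, passed the interaction test of phloem-like cells against the other cells (log2 difference -3.13, adjusted p = 0.0332, edgeR, lower in 5 of 5 elicitor libraries). It was also among the 10 leading genes of the endodermis-like cluster 20 at the finer resolution. In Mock 1 and Mock 2 it had 151 and 449 CPM in endodermis-like cells against 22.6 and 45.6 CPM in phloem-like cells. The call ended at a finer cluster resolution and when any single library was left out. In phloem-like cells the gene had 45 UMIs in Mock 1 and 76 in Mock 2, against 4 to 13 in the elicitor libraries. Casparian strip genes together had 1409 UMIs in phloem-like cells of Mock 1, in 15 of 83 cells, 76 in Mock 2, in 17 of 130 cells, and 7 to 38 in the elicitor libraries. The tenth of Mock 1 phloem-like cells richest in them held 99.6 percent of these UMIs, where spreading by cell depth gave 40.2 percent, and in Mock 2 94.7 against 55.0 percent. With a class by version term CASP2, CASP5, UCC1 and OCT3 passed in phloem-like cells as well. Few phloem-like cells of either Mock library thus held the Casparian strip UMIs, and whether the peroxidase UMIs lay in the same cells, or why, was not tested. The call therefore does not show a response of phloem cells.

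Mock 2 and Mock 1 lay 2-fold apart in 4007 genes. A heat shock response to handling in the second set was argued against by its list, whose median in Mock 2 over Mock 1 was at most 0.47 in any of 11 classes, but other stress stays open, since kept cells of Mock 2 had 1.46 percent mitochondrial UMIs against 0.340 in Mock 1 and the early immunity median was 1.54. With equal class shares 36.7 percent of the number of genes remained, so different shares of root cells may account for part of the gap, and what sets the rest apart stays open. The Cell Ranger version follows the same split, and whether the day or the preparation does is not given. No biological explanation was tested, since both libraries are Mock.

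flg22 and Chitin moved fewer genes than Pep1, SCOOP10 and SCREW1. Depth was argued against, since Chitin had more UMIs than SCOOP10 (a difference of 39.6, in units of 1e6 UMIs). The 120 genes raised by both SCOOP10 and SCREW1 had a median of 0.58 with flg22 over Mock 1 (random lists at most 0.03), as predicted for a treated library. Random lists do not move together as such genes can, and the Mock libraries also lay apart in immunity genes with no elicitor. The test therefore cannot decide whether the flg22 library was untreated. For Chitin the genes raised by Pep1 had a median of -0.10 over Mock 2, below every random list (median 0.07), while 3 of 4 genes at least 2-fold higher with Chitin were also higher with Pep1 (0.139 for independent lists), so an untreated or inactive Chitin sample and a response through other genes cannot be told apart. A lower receptor level may contribute, since FLS2 lay below PEPR1 in Mock 1 and the lower of MIK2 and NUT had 3.05 times the CPM of the higher of CERK1 and LYK5 in Mock 2 (locus codes of MIK2 and NUT assigned by hand). In Mock 1, however, PEPR1 had 19.1 CPM against 19.3 for CERK1 and 14.4 for LYK5, and Pep1 moved many genes. For Chitin a low receptor level is therefore left open rather than favoured. The elicitor itself remains an untested biological explanation.

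Root hair genes were lower with Pep1 than in Mock 1, and Casparian strip genes lower with Chitin, SCOOP10 and SCREW1 than in Mock 2. Fewer trichoblast cells as the whole cause were argued against by a median of -2.44 for trichoblast markers within trichoblast-like cells, and fewer cells of cluster 28, which root hair genes lead, by -1.55 within it, although flg22 also gave -0.60 and -0.48 and the shares were smaller with Pep1 (4.94 against 6.34 percent, and 0.835 against 1.38 percent for the cluster), which may account for part. Fewer endodermis-like cells as the whole cause were argued against by Casparian strip medians within that class, of which the highest was -2.21 (Chitin). Within cluster 17, which held nearly all these UMIs, Casparian strip genes together had 4840 CPM in Mock 2 and 3326, 4791 and 3222 in Mock 1, flg22 and Pep1, against 1250, 785 and 757 with Chitin, SCOOP10 and SCREW1, so a lower level with these 3 may be a response, a hypothesis found and tested on the same libraries. A difference between single libraries in root age or position, which has no replicate here, stays open for both patterns.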

How the results depend on the processing

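The fits with the Cell Ranger version, with a class by version term and without cells of high doublet score were chosen after the results were seen, and the other alternatives before. For the causes of the changes given here, the cause was not tested. In the test of treated against Mock 0 genes passed in all 18 alternatives, of edgeR or DESeq2 (unadjusted counts from 97 to 2196). Keeping called doublets, counted among these, repeats the main fit, since no doublet was called. Genes passing for flg22, Pep1, Chitin, SCOOP10 and SCREW1 were 0, 21, 0, 32 and 32 with the size factors of DESeq2, 2 (flg22), 63 (Pep1) and 6 (Chitin) with DESeq2 itself, and 0 for each elicitor with the dispersion of treated against Mock and a likelihood ratio test in edgeR, also without either Mock library (0 to 0, with 43 to 1598 at an unadjusted p under 0.05). For Chitin 2 passed with no filter and 2 with all barcodes. Genes at least 3-fold from both Mock libraries were 1, 76, 2, 103 and 105, and at 50 CPM the 2-fold counts were 22, 112, 7, 105 and 102. Leaving out either Mock library gave 60 to 3444 for flg22, 635 to 3271 for Pep1, 66 to 2885 for Chitin, 379 to 3605 for SCOOP10 and 454 to 3219 for SCREW1. Within classes 2 genes passed without cells of high doublet score, and 0 to 6 with 1 library left out. Of interactions 0 passed at finer clusters, 6 with a class by version term and 0 to 1 with 1 library left out. Lists passing by camera were 4 with the version as a covariate and 0 to 10 with 1 library left out. With 1 library left out the adjusted p ranged from 2.92e-11 to 0.819 for early immunity, 1.45e-09 to 0.398 for receptors, 0.000124 to 0.286 for jasmonate, 5.28e-05 to 0.566 for salicylic acid and 0.000159 to 0.278 for cell division, and these 5 lists reversed without Mock replicate 1, which gave the highest p. The median correlation between elicitors was -0.10 at 50 CPM and 0.54 to 0.60 without either Mock library. XTH14 with SCREW1 reversed, to a log2 of 0.25, without Mock replicate 1. Of the other values for 36 gene and elicitor pairs, 114 kept their side of the threshold and 137 kept their direction but missed it. For lists 115 kept both, 18 missed the threshold and 5 passed it anew. With the estimated correlation 0 lists passed in any of 11 alternatives. Depth limits genes under 0.0348 CPM in Mock 2.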

Other observations

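Markers of xylem and endodermis were described in values chosen after they were seen. In xylem-like cells AT4G08160 passed the interaction test with a class by version term (adjusted p = 0.0157, edgeR) and TED6 without Pep1 (adjusted p = 0.0428, edgeR), and the other values have no test. AT4G08160 in xylem-like cells had 112 CPM in Mock 1, 86.6 with flg22 and 64.4 with Pep1, and 125 CPM in Mock 2 against 4.77 with Chitin, 7.89 with SCOOP10 and 12.3 with SCREW1. TED6, a gene of tracheary element differentiation, had 126 CPM in Mock 1, 75.9 with flg22 and 70.6 with Pep1, and 168 CPM in Mock 2 against 2.39, 2.63 and 1.17 CPM with Chitin, SCOOP10 and SCREW1. In endodermis-like cells CASP2, a Casparian strip scaffold protein, had 301 CPM in Mock 2 against 32.1 with Chitin, 27.7 with SCOOP10 and 62.6 with SCREW1, and CASP5 had 435 against 96.9, 66.4 and 104 CPM. In the first set CASP2 had 31.9 CPM in Mock 1, 89.6 with flg22 and 97.4 with Pep1, and CASP5 29.9, 40.9 and 42.0. The class was made up differently in the sets, mostly of cluster 14 in Mock 1 and of cluster 17 in Mock 2. Within cluster 17 CASP2 had 271, 543 and 467 CPM in Mock 1, flg22 and Pep1 and 564 in Mock 2, against 79.2, 70.6 and 91.7 with Chitin, SCOOP10 and SCREW1, while CASP5 had 816 CPM in Mock 2 and 153 to 254 CPM in the other libraries.

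Heat shock genes had a median log2 fold change over the Mock library of the set of -0.68 with flg22, 0.10 with Pep1, 0.37 with Chitin, 0.50 with SCOOP10 and 0.69 with SCREW1. HSP17.6II had 37.6 CPM in Mock 1 and 22.3 with flg22, and 20.9 CPM in Mock 2 against 50.8 with SCREW1. Among cell division genes, CDC20.1, an activator of the anaphase-promoting complex, had 22.8 CPM in Mock 2 and 7.28 with SCREW1, where dividing cells also gave the largest number of raised genes of the 11 classes with SCREW1. Dividing cells made up 3.01 percent of Mock 2 (Wilson interval 2.59 to 3.49) and 2.35 percent of SCREW1 (2.06 to 2.68). Whether this smaller share accounts for part of the fall was not tested.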
